A study of Mus musculus with 21 samples.

How the data were processed

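RNA-seq of mouse liver was taken from 4 genotypes in 3 conditions, which makes 12 groups. Per the labels, WT animals carried the floxed Ezh2 gene without Cre, E1KO lacked Ezh1, E2KO had lost Ezh2 in hepatocytes through Alb-Cre, and DKO combined both losses. The conditions were 2 months of age, 8 months of age, and 3 months of age with CCl4 (carbon tetrachloride, a liver toxin that hepatocytes activate). The background was mixed (129SV::FVB/N::C57BL/6). Libraries were made from 1 ug of total RNA with the TruSeq kit and SuperScript II.

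The authors deposited 1 table of FPKM values (fragments per kilobase of gene model scaled to the mapped fragments of the library) with 22520 genes and 12 columns, 1 per group, to 2 decimals. The sample titles name 3 replicates per group, or 2 at 8 months. How the replicates were combined is not given in the sources used here, so no spread between animals can be had. The submitters' notes name CASAVA, TopHat and Cufflinks, with BWA, SICER and HOMER for the series as a whole, on mouse assembly mm9. Their versions, and the part each played for the RNA, are not given in the sources used here. Read counts cannot be recovered from the table, so the depth is unknown and no counting interval is given. Column totals ran from 531761 to 674119 FPKM, and the 10 most abundant genes held 12.2% to 19.1% of a column. The 9 ChIP-seq samples of the series (H3K4me3, H3K27me3 and a pooled input) are not analysed here.

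Genes of at least 1 FPKM in at least 2 columns were tested, which left 11394. Of the 22520 genes, 2405 were at 0 in every column. For genes near the limit the filter favours those high in the DKO columns, so the list members that pass it without these columns were counted apart, a check added after the values were seen. Values were used as log2(FPKM+1) on the deposited scale. A linear model with additive terms for genotype and condition was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend in mean expression), with 6 residual degrees of freedom. With 1 value per group, the spread is the departure of the 12 values from the additive fit, so it holds genotype-by-condition differences as well as noise. Adjusted p is by Benjamini-Hochberg over all tested genes at a threshold of 0.05, two-sided. Contrasts were DKO, E1KO and E2KO each against WT, DKO against E2KO, the non-additivity DKO - E1KO - E2KO + WT, and 8 months and CCl4 each against 2 months. A second fit with DKO-by-condition terms compared the DKO difference at 8 months, and with CCl4, with that at 2 months. It had 4 residual degrees of freedom, from the WT, E1KO and E2KO columns. These genotypes share the condition terms, so the DKO difference in this fit is from their average rather than from WT alone. Within a condition, a gene counted as different when log2(FPKM+1) differed by at least 1. That rule has no test and no replicate check. Genes past it in a pair of conditions were counted beside the number that independence would give, and Spearman correlations were taken across genes, which are not independent replicates.

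The tests, contrasts, 34 gene lists, named-gene rule and most alternatives were fixed before the data were examined. The lists covered PRC2 subunits, Hox genes, developmental transcription factors known as Polycomb targets, CDK inhibitors, cell cycle genes, fibrillar collagen and matrix genes, stellate cell and myofibroblast markers, cholangiocyte and progenitor markers, macrophage and Kupffer cell markers, and lymphocyte, neutrophil and sinusoidal endothelial markers. They also covered hepatocyte secreted protein genes, fetal liver and oncofetal genes, xenobiotic P450 genes, bile acid genes, lipogenic and cholesterol synthesis genes, fatty acid oxidation genes, lipid droplet and uptake genes, urea cycle and amino acid catabolism genes, gluconeogenesis genes and pericentral genes. The rest were chemokines and cytokines, acute phase genes, p53 targets, unfolded protein response genes, NRF2 targets, interferon-stimulated genes, male-biased and female-biased liver genes, circadian clock genes, pancreatic acinar genes, erythroid genes, and adipose and muscle genes. Lists were written from general knowledge of liver biology and some genes are in more than 1 list. Several abundant list members (among them Alb, Ttr, Trf, Apoa1, Apoa2, Ahsg, Mup1, Mup2, Mup3 and Mup7) have no value in the table and are not analysed here. Each list was tested with camera from limma, with its preset inter-gene correlation of 0.01 and with an estimated correlation, with Benjamini-Hochberg over the 34 lists. List members past the threshold were counted over all genes tested and adjusted over the list alone. Within a condition, a list's median difference was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Such percentiles describe these libraries and test nothing about animals.

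Genes were named by rule. They were Ezh1 and Ezh2; for each additive contrast with genes past the threshold, the 10 largest rises and 10 largest falls with the same sign in every condition (or genotype); for each condition, the 5 largest rises and falls of DKO against WT; and from each list up to 4 members with the largest absolute DKO difference. Predicted genes (Gm and Rik symbols), microRNA and snoRNA entries were passed over in the contrast and condition parts, and so were clone-style, LOC and numeric names. Genes named outside the rule were chosen after their values were seen; they are further members of the lists, the genes given for DKO by condition, and the few genes behind counts of 5 or fewer. Some genes that the rule selects are not reported here. A simulation put shifts of known size into values made from the additive fit plus independent normal noise at each gene's residual spread. For DKO against WT a shift was the same in every condition. Departures from the additive fit in the data need not behave like such noise, so the rates hold for that model. For DKO against WT, limma called 32.4% of genes shifted by 0.5, 82% of those shifted by 1 and 94% of those shifted by 2 on the log2 scale, with 38 false calls among 55970 unshifted genes. For DKO by condition at 8 months it called 14% of genes shifted by 1 and 64.4% of those shifted by 2, and DKO by CCl4 was not simulated. Of the lists tested on simulated data, camera called 5 of 5 shifted by 0.5 and 0 of 165 others, with genes made independent.

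Alternatives were a pseudocount of 0.1, no filter on low values, each column rescaled by its median ratio (factors 0.956 to 1.06), eBayes without trend, leaving out each condition or genotype, only the WT and DKO columns, sizes of 1.5-fold and 4-fold, and an estimated correlation for the lists. Leaving out the 8-month column labelled E1KO was added after the data were seen. Gene order for 1 check came from mouse assembly GRCm38.p6, in which 11323 of the 11394 tested genes (99.4%) were found by symbol. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.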

Results

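The livers of 4 genotypes were compared at 2 months, at 8 months and at 3 months with CCl4, with 1 FPKM value per gene and group. Ezh1 and Ezh2 are the alternative catalytic subunits of PRC2, the Polycomb complex that writes the repressive histone mark H3K27me3. CCl4 set the columns apart more than genotype or age did. The first principal component held 51.5% of the variance and placed the CCl4 columns at 44.1 to 60.5 and all others at -33.2 to -18.0. On the second component (11.1%), DKO lay lowest in each condition, at -15.2 at 2 months, -41.6 at 8 months and -26.2 with CCl4. The third (9.28%) placed the 2-month columns at 9.11 to 25.4 and the 8-month columns at -27.1 to -9.96. Spearman correlations across genes were 0.958 to 0.980 among WT, E1KO and E2KO of 1 condition and 0.932 to 0.977 between DKO and these. They were 0.932 to 0.965 between 2 and 8 months, and 0.853 to 0.900 between CCl4 and the other conditions. There is 1 value per group throughout, so no value carries a spread between animals.

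Ezh1 RNA was 2.38 FPKM in WT at 2 months and 0.07 in both E1KO and DKO, which is 2.94% of WT. With CCl4 it was 9.76% of WT in E1KO and 13.2% in DKO. At 8 months it was 2.94% of WT in DKO but 43.1% in the column labelled E1KO (0.88 against 2.04 FPKM). Ezh2 RNA was low in untreated WT liver (1.11 FPKM at 2 months and 0.91 at 8 months) and 5.68 FPKM with CCl4. In E2KO it was 75.7%, 86.8% and 69% of WT at 2 months, 8 months and with CCl4, and in DKO 66.7%, 139.6% and 44.2%. In E1KO, where Ezh2 is not deleted, it was 72.1%, 85.7% and 82.4%. At 2 and 8 months Ezh2 RNA therefore did not set E2KO apart from E1KO. These are gene-level values from whole liver, where cells other than hepatocytes keep Ezh2, and the deleted exons cannot be seen in them.

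**Figure D1:**
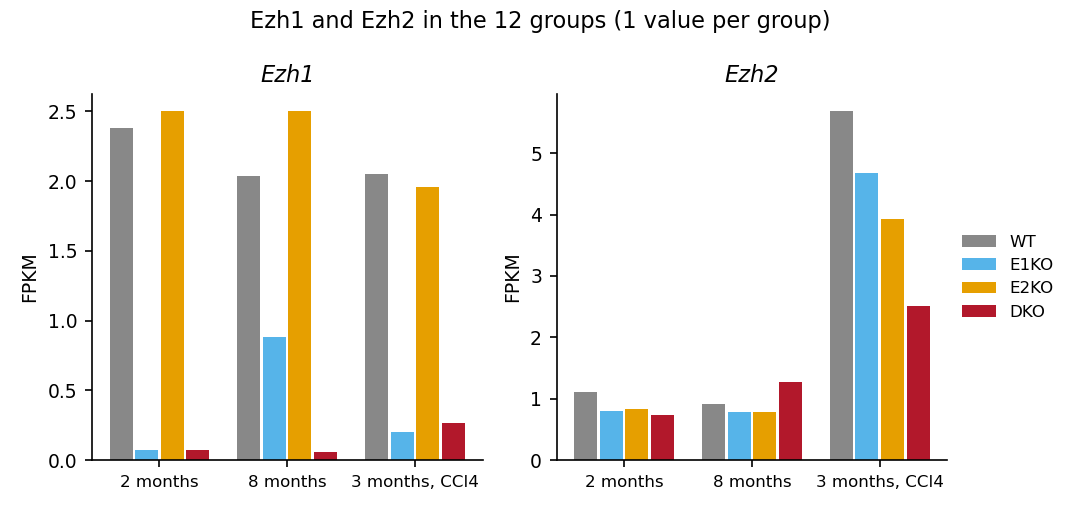
Bars show FPKM of Ezh1 (left) and Ezh2 (right) in the 12 groups, 1 value per group, by condition and genotype. Ezh1 was at most 0.27 FPKM in the E1KO and DKO columns except for the 8-month column labelled E1KO at 0.88, and Ezh2 was highest with CCl4, at 5.68 in WT.

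DKO against WT first answers which genes liver expresses differently when Ezh1 is lost and Ezh2 is deleted in hepatocytes, and also whether fibrosis genes, lipid genes and hepatocyte functions move. Hoxa10, Hoxc10, Hoxd9, 6 developmental transcription factors and the cell cycle inhibitor gene Cdkn2a rose, all from low levels. The fetal liver genes Gpc3, Scd2, Tff3 and Igf2bp3 rose, and so did 7 matrix genes such as Col14a1 and Dcn. The female-biased liver genes Cyp2a4 and Sult2a1 rose while the male-biased genes Mup21 and Elovl3 fell. In all, limma called 206 genes higher and 93 lower among 11394, of which 84 rose and 25 fell by at least 2-fold. The calls need all 3 conditions: 23 genes passed without 2 months, 37 without 8 months and 25 without CCl4. With only the WT and DKO columns in the fit, 5 genes passed, 3 higher and 2 lower.

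Of 39 listed Hox genes, which set position along the body axis, only 4 passed the filter on low values, and 3 of these rose: Hoxa10 by 2.11 (adjusted p = 0.0191), Hoxc10 by 1.51 (0.0271) and Hoxd9 by 1.43 (0.0306), on the log2 scale as throughout. Hoxd8 differed by 1.05 without passing (0.0609), and all 4 passed adjusted over the list alone. No Hox gene reached 1 FPKM in any WT, E1KO or E2KO column, against 1, 5 and 9 of 39 in DKO at 2 months, 8 months and with CCl4, so the filter let in only genes that are higher in DKO. The list result (camera adjusted p = 3.86e-06; adjusted p = 0.205 with an estimated correlation) therefore had its direction set by the filter and is given as a value only. With no filter on low values Hoxa10 (adjusted p = 0.0292), Hoxc10 (0.0356) and Hoxd9 (0.0416) still passed. Of 81 developmental transcription factors known as Polycomb targets 8 passed the filter, 4 of them only through the DKO columns, and 6 rose, or 7 adjusted over the list alone (median 0.93, camera adjusted p = 1e-08; adjusted p = 0.0963 with an estimated correlation). Among them, Sim2 rose by 1.34, Gsc by 1.14 and Twist1, a mesenchymal factor, by 0.94; Twist1 did not pass without the filter (adjusted p = 0.0599). Of 7 CDK inhibitors, Cdkn2a rose by 2.45 (adjusted p = 0.0197) and Cdkn1c by 1.08 (0.034), and 3 did so adjusted over the list alone. Cdkn2a was listed at 0 in WT at 2 months and at 1.4 FPKM in DKO, and went from 0.11 to 7.87 FPKM at 8 months and from 0.29 to 9.97 with CCl4. The CDK inhibitors had a camera adjusted p = 0.00534 upward (adjusted p = 0.253 with an estimated correlation), with list medians of 0.57 at 2 months, 0.95 at 8 months and -0.37 with CCl4. Cdkn2a and Cdkn2b passed the filter only through the DKO columns, and the other 5 had a median of 0.21. Of 10 PRC2 subunits only Ezh1 passed, at -1.48 (adjusted p = 0.0106), and 3 fell adjusted over the list alone (camera adjusted p = 0.0544; adjusted p = 0.391 with an estimated correlation).

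Of 11 tested fetal liver and oncofetal genes, 4 rose and none fell (median 1.23, camera adjusted p = 1.37e-05; adjusted p = 0.0467 with an estimated correlation). The filter favours rises here as well: 3 of the 11, Igf2bp3 among them, passed it only through the DKO columns, and the other 8 had a median of 0.68 with 6 higher. Gpc3, a heparan sulphate proteoglycan of fetal liver and hepatocellular carcinoma, rose by 2.43 (adjusted p = 0.0392) and reached 32.25 FPKM in DKO with CCl4 against 1.09 in WT. Scd2, a fatty acid desaturase of fetal liver, rose by 2.51 (0.00286), the secreted peptide gene Tff3 by 2.49 (0.00552) and the RNA-binding protein gene Igf2bp3 by 1.88 (0.0127). Gpc3 did not pass without the filter on low values (adjusted p = 0.0568). H19, a fetal non-coding RNA, differed by 2.09 without passing (0.218). Its value of 13 FPKM in the 8-month column labelled E1KO adds to its spread in this fit.

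Of 41 matrix genes, 7 rose, none fell and 20 rose adjusted over the list alone (median 0.46, camera adjusted p = 7.29e-13; adjusted p = 0.166 with an estimated correlation). Those that passed were Col14a1 (0.87), Bgn (0.71), Mmp2 (0.66), Fbln1, Dcn, Col6a1 and Timp2, while Col3a1, a main collagen of scars, stood at 1.29 without passing (adjusted p = 0.0591). Of 18 stellate cell and myofibroblast markers, Hand2 rose by 0.91 and 5 rose adjusted over the list alone (camera adjusted p = 5.81e-05; adjusted p = 0.13 with an estimated correlation). Of 18 cholangiocyte and progenitor markers, Cldn7 rose by 1.95 (0.0104) and Krt23 by 1.74 (0.0262), and 6 rose adjusted over the list alone (camera adjusted p = 0.00156; adjusted p = 0.391 with an estimated correlation). Their median DKO difference was 0.087 at 2 months, 0.92 at 8 months and -0.037 with CCl4, and 4 passed the filter only through the DKO columns (median of the other 14 across conditions 0.21). Of 28 macrophage markers 1 rose over all genes and 1 adjusted over the list alone (median 0.46, camera adjusted p = 8.39e-09; adjusted p = 0.391 with an estimated correlation). The lymphocyte gene Nkg7 rose by 0.90, and 2 of 5 lymphocyte markers, of which 2 passed the filter only through the DKO columns, passed adjusted over the list alone (camera adjusted p = 0.000813; adjusted p = 0.258 with an estimated correlation). No neutrophil marker passed over all genes and 2 of 5 did adjusted over the list alone (camera adjusted p = 0.0274; adjusted p = 0.527 with an estimated correlation). No chemokine or cytokine of 22 passed (camera adjusted p = 0.0193; adjusted p = 0.606 with an estimated correlation). The median of this list was -0.26 at 2 months, 0.51 at 8 months and 0.46 with CCl4. Of 30 interferon-stimulated genes, Gbp2 rose by 0.68, and 2 passed adjusted over the list alone (camera adjusted p = 9.72e-06; adjusted p = 0.517 with an estimated correlation).

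Of 20 tested female-biased liver genes, 5 rose, none fell and 13 rose adjusted over the list alone (median 1.70, camera adjusted p = 4.52e-14; adjusted p = 0.073 with an estimated correlation). Of the 20, 6 such as Sult2a1 passed the filter only through the DKO columns, and the other 14 were all higher (median 1.63). Cyp2a4, a steroid hydroxylase, rose by 5.84 (SE 0.60, adjusted p = 0.00552), from 0.39 to 124.3 FPKM at 2 months, 1.65 to 123.6 at 8 months and 3.36 to 191 with CCl4. The sulfotransferase gene Sult2a1 rose by 4.94 (0.00158), Sult2a2 by 3.62 (0.013), A1bg by 2.62 (0.0296) and the steroidogenic enzyme gene Cyp17a1 by 1.93 (0.0121). Of 20 male-biased genes, 4 fell, and adjusted over the list alone 12 fell and 1 rose (median -0.73, camera adjusted p = 9.72e-06; adjusted p = 0.0467 with an estimated correlation). Mup21, a major urinary protein gene, fell by 3.58 (0.00233), from 1624 to 112.3 FPKM at 2 months. The fatty acid elongase gene Elovl3 (-1.95, 0.0106), Ugt2b1 (-1.31, 0.0106) and the oxysterol hydroxylase gene Cyp7b1 (-1.20, 0.0234) also fell. Xist, expressed from the inactive X of females, was 0.01 to 0.03 FPKM in all 12 columns. The median DKO to WT ratio of 4 Y-linked genes was 0.887 at 2 months, 0.852 at 8 months and 0.892 with CCl4. Sult2a1 and Sult2a2, Cyp2a4 and Cyp2a5, the Mup genes, Gstp1 and Gstp2, and the Ugt1a isoforms are near-identical, and how shared reads were assigned is not given in the sources used here, so which member of each changed is uncertain.

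Of 24 lipid droplet and uptake genes, Lpl passed over all genes; adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.418; adjusted p = 0.721 with an estimated correlation). Lpl, the lipase that frees fatty acids from circulating triglyceride, rose by 3.24 (adjusted p = 0.00834), with 7.86 FPKM in WT and 90.2 in DKO at 2 months, 1.65 and 39.6 at 8 months, and 9.59 and 55.5 with CCl4. None of 33 lipogenic and cholesterol synthesis genes passed (camera adjusted p = 0.979; adjusted p = 0.992 with an estimated correlation). Of 28 fatty acid oxidation genes only Hadhb, a beta-oxidation subunit, fell, by 0.47 (camera adjusted p = 0.825; adjusted p = 0.929 with an estimated correlation). Of 32 xenobiotic P450 genes, Cyp2a4, Cyp2c55 (2.16) and Cyp2b10 (1.35) rose and Cyp2j5 fell by 0.62, with 5 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.159; adjusted p = 0.721 with an estimated correlation). Of 20 bile acid genes, Cyp7b1 and the conjugating enzyme gene Baat (-0.73, adjusted p = 0.0174) fell (camera adjusted p = 0.182; adjusted p = 0.706 with an estimated correlation). Of 27 NRF2 targets 4 fell, all detoxification enzymes: Gstp1 (-1.30, 0.009), Gstm4 (-0.93), Aox1 (-0.83) and Txnrd1 (-0.59; camera adjusted p = 0.204; adjusted p = 0.721 with an estimated correlation). Of 26 acute phase genes, Orm3 rose by 2.23 (0.0197), the hepcidin gene Hamp2 by 1.73 (0.0457) and Cebpd by 0.68 (camera adjusted p = 0.286; adjusted p = 0.771 with an estimated correlation). The list differed by condition, with 12 members at least 2-fold lower and 2 higher in DKO at 2 months (median -0.95) and medians of 0.18 at 8 months and 0.54 with CCl4. At 2 months the acute phase members Saa2 and Mt1 were far below WT in E1KO and E2KO too (values under Other observations). Their low DKO values are therefore not particular to DKO.

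Among 27 hepatocyte secreted protein genes, the clotting factor gene F11 fell by 1.06 (adjusted p = 0.0314; camera adjusted p = 0.373; adjusted p = 0.828 with an estimated correlation). None of 28 urea cycle genes (camera adjusted p = 0.329; adjusted p = 0.721 with an estimated correlation) or 15 gluconeogenesis genes (0.22; adjusted p = 0.721 with an estimated correlation) passed over all genes. Nkd1, a Wnt feedback gene, rose by 0.47 among 19 pericentral genes, of which 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.606 with an estimated correlation). None of 19 sinusoidal endothelial markers passed (camera adjusted p = 0.182; adjusted p = 0.721 with an estimated correlation), nor did any of 25 unfolded protein response genes (0.713; adjusted p = 0.929 with an estimated correlation). The clock gene Per1 rose by 0.91, and 3 of 21 clock genes rose adjusted over the list alone (camera adjusted p = 0.0429; adjusted p = 0.527 with an estimated correlation). Sulf2, a heparan sulphatase, rose by 0.86 among 23 p53 targets (camera adjusted p = 0.0855; adjusted p = 0.606 with an estimated correlation). The lipase-related gene Pnliprp1 rose by 1.5 among 3 tested pancreatic acinar genes (camera adjusted p = 0.463; adjusted p = 0.706 with an estimated correlation). No erythroid gene of 6 passed (camera adjusted p = 0.286; adjusted p = 0.606 with an estimated correlation), and no adipose or muscle gene of 3 (0.885; adjusted p = 0.929 with an estimated correlation). None of the 41 cell cycle genes passed, although 40 had negative differences (median -0.38, camera adjusted p = 0.00515; adjusted p = 0.721 with an estimated correlation). Their median was 0.055 at 2 months, 0.18 at 8 months and -1.48 with CCl4, so the negative average came from CCl4 alone. Median, mean and camera direction differed in sign only in lists that camera did not call: endothelial, lipogenic, fatty acid oxidation, urea cycle, acute phase, unfolded protein response, pancreatic, and adipose and muscle genes.

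Outside the lists, the epithelial protease inhibitor gene Wfdc2 rose by 3.17 (adjusted p = 0.00807) and the MHC class I gene H2-Q1 by 2.53 (0.0106). The ion channel gene Accn5 (-3.17, 0.0198), Serpina4-ps1 (-2.79), the adipokine gene Serpina12 (-2.63), the antigen-presenting gene Cd1d2 (-2.12), Ugt1a9 (-1.80), Gstp2 (-1.78), Nlrp12 (-1.68) and the glutamate transporter gene Slc17a8 (-1.57) fell. All of these had the same sign in 3 of 3 conditions. With no filter on low values Serpina4-ps1 (adjusted p = 0.0611), Serpina12 (0.0601) and Nlrp12 (0.0687) lost their call, and so did Hamp2 (0.0632), Gbp2 (0.0632) and Gstm4 (0.051) of the lists.

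**Figure D2:**
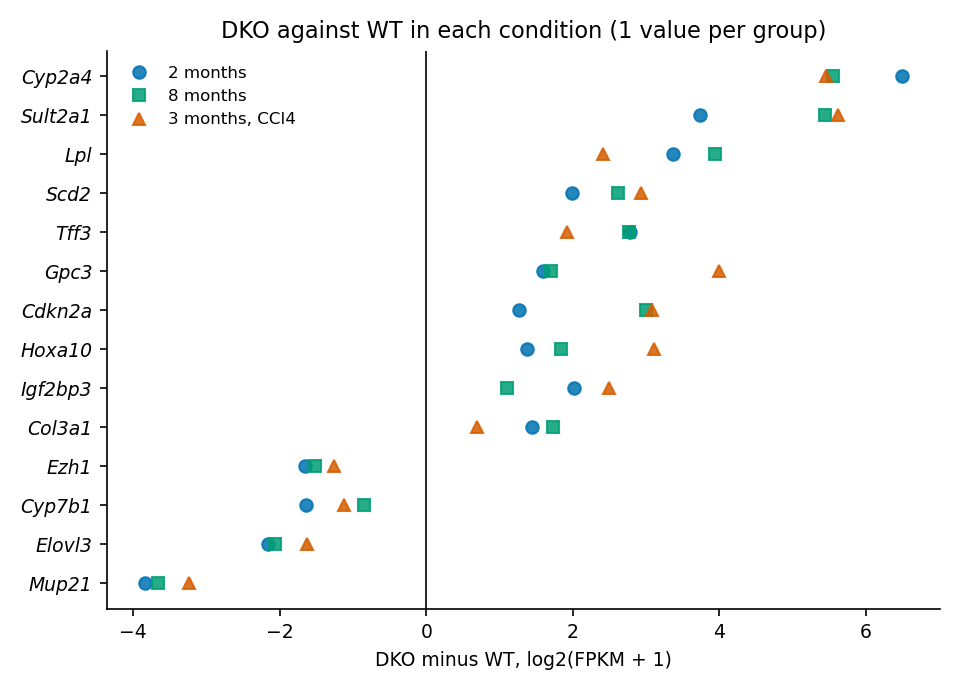
Points show the DKO minus WT difference in log2(FPKM+1) for 14 genes named in the text, 1 point per condition, with no replicates behind a point; Col3a1 did not pass across conditions. Cyp2a4 and Sult2a1 lay above 0 and Mup21 below 0 in all 3 conditions (fitted differences 5.84, 4.94 and -3.58).

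E1KO against WT answers what loss of Ezh1 alone changes. Hardly any single gene passed, and none of the 34 lists passed with an estimated correlation, against 7 with the preset one. Ezh1 itself did not pass with all columns in the fit, so the low count does not show that little changes. limma called 2 genes, both higher: AA465934 (2.43, adjusted p = 0.00813) and Gm15698 (1.01, adjusted p = 0.0222), with 640 at an unadjusted p under 0.05. Both lie on chromosome 11 near Ezh1, 179 and 118 tested genes away, in a stretch where linkage to the null allele cannot be told apart from loss of Ezh1. All 28 macrophage markers were higher (median 0.35, camera adjusted p = 9.83e-13; adjusted p = 0.537 with an estimated correlation), as were 39 of 41 matrix genes (1.17e-10; adjusted p = 0.47 with an estimated correlation) and 26 of 30 interferon-stimulated genes (8.24e-05; adjusted p = 0.817 with an estimated correlation). The 8-month column labelled E1KO held skeletal muscle genes at 416.9 FPKM in sum, against 0.98 to 1.84 in the other 11 columns (Acta1 128.9, Ckm 52.5). Without that column, 4 genes passed: AA465934, Ezh1 (-1.49, adjusted p = 0.0279), Gm12238 and Mir5100. Leaving out 1 condition left 0 to 4 genes, with 4 without CCl4, 0 without 2 months and 0 without 8 months.

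E2KO against WT answers what loss of Ezh2 in hepatocytes alone changes. limma called 0 genes, with 155 at an unadjusted p under 0.05. Cdkn2a was at most 0.15 FPKM and Gpc3, Sult2a1 and Cyp2a4 did not pass in E2KO. Unfolded protein response genes were higher as a list (camera adjusted p = 0.00141; adjusted p = 0.832 with an estimated correlation), and endothelial markers lower (0.0022; adjusted p = 0.832 with an estimated correlation). Cell cycle genes were lower as a list (camera adjusted p = 0.00921; adjusted p = 0.839 with an estimated correlation), and so were interferon-stimulated genes (0.00875; adjusted p = 0.839 with an estimated correlation). Of the 14 lists called, none passed with an estimated correlation.

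DKO against E2KO answers what loss of Ezh1 adds once Ezh2 is deleted in hepatocytes. The female-biased genes Cyp2a4 (6.23, adjusted p = 0.00398) and Sult2a1 (5.02, 0.00109) rose, as did Lpl (3.44), Tff3 (3.16), Calml4 (3.11), H2-Q1 (3.02) and Scd2 (2.69). Mup21 (-3.44, 0.0024), Mup20 (-2.69, 0.0384), the apolipoprotein gene Apom (-1.95, 0.00604), Ugt1a9 (-1.93), Elovl3 (-1.92), the peptide hormone gene Enho (-1.79), Lcn13 (-1.69) and Ezh1 (-1.55) fell. Col3a1 passed here (1.5, 0.0374). In all, limma called 236 genes higher and 112 lower. Without 2 months 23 genes passed, without 8 months 47, without CCl4 23, and without the 8-month column labelled E1KO 231. Calml4 and Mup20 lost their call with no filter on low values. Fetal liver genes rose, 4 of 11 over all genes and 5 adjusted over the list alone (median 1.89, camera adjusted p = 2.71e-07; adjusted p = 0.0358 with an estimated correlation), with a median of 1.39 in the 8 that pass the filter without the DKO columns. Male-biased genes fell, 5 of 20 over all genes and 11 adjusted over the list alone (camera adjusted p = 9.89e-06; adjusted p = 0.0358 with an estimated correlation). Female-biased genes (4.95e-12; adjusted p = 0.104 with an estimated correlation; median 1.56 in the 14 that pass the filter without DKO) and matrix genes (1.1e-11; adjusted p = 0.171 with an estimated correlation) were higher with the preset correlation.

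The non-additivity contrast answers whether the double loss exceeds the sum of the single losses. limma called 4 genes, all higher, at adjusted p = 0.0298, with 776 at an unadjusted p under 0.05. These were Sult2a1 (5.08), Tff3 (3.37), the transporter gene Slc16a5 (1.88) and Aldh1a2 (1.52), which makes retinoic acid. At 2 months, Tff3 was 9.92, 15.2, 5.81 and 74.1 FPKM in WT, E1KO, E2KO and DKO. Fetal liver genes were higher as a list, with 1 of 11 past the threshold over all genes and 4 adjusted over the list alone (median 0.79, camera adjusted p = 1.08e-07; adjusted p = 0.0302 with an estimated correlation). Of the 11, 3 passed the filter through DKO columns only, and the other 8 had a median of 1.40. Sult2a1 and Tff3 lost their call with no filter on low values, and Tff3 and Aldh1a2 with a pseudocount of 0.1. Adjusted over the list alone, 3 CDK inhibitors (list 2.71e-05; adjusted p = 0.117 with an estimated correlation) and 5 female-biased genes (list 3.74e-14; adjusted p = 0.0742 with an estimated correlation) were higher. Without the 8-month column labelled E1KO, 1 gene passed, Gm12238, and none of these 4 did. Without 2 months 9 genes passed, without 8 months 1 and without CCl4 2.

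Within each condition, DKO differed from WT by at least 2-fold in 227 genes upward and 169 downward at 2 months, 326 and 139 at 8 months, and 334 and 282 with CCl4. These are differences between single columns with no replicate check. At 2 months the largest positive differences were Cyp2a4 (6.49), Cyp2b9 (4.71), Hao2 (4.70) and Cyp4a14 (4.29), and Bc1 was listed at 0 in WT. The largest negative differences were Saa2 (-4.74), an acute phase gene at 2175 FPKM in WT and 80.2 in DKO, Mt2 (-4.12), Mup21 (-3.84), Accn5 (-3.41) and Serpina4-ps1 (-3.02). Saa2 was far below WT in E1KO and E2KO too. At 8 months the metallothionein genes Mt1 (5.70) and Mt2 (5.68) stood highest beside Cyp2a4 (5.55) and Ly6d (5.55), with Rnu73b listed at 0 in WT. Lowest there were Slco1a1 (-5.92), Hsd3b5 (-5.0), Mup21 (-3.66) and Accn5 (-3.64), and Bc1 was listed at 0 in DKO. With CCl4 the extremes were Sult2a1 (5.62), Cyp2a4 (5.46), Cyp2b9 (5.27), Sult2a2 (4.68) and the prostaglandin synthase gene Ptgds (4.12), against Serpina3c (-5.25), Cyp21a1 (-3.91), Hsd3b5 (-3.73), Mup20 (-3.60) and Serpina4-ps1 (-3.27).

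Genes past 2-fold in DKO were shared between conditions in these numbers. At 2 and 8 months 100 genes were higher in both, where 6.49 would be by independence, and 40 lower (2.06). At 2 months and with CCl4 the shared counts were 97 (6.65) and 39 (4.18), and at 8 months and with CCl4 104 (9.56) and 37 (3.44). In all 3 conditions 52 genes were higher and 20 lower. At 2 and 8 months 10 genes were higher in the first and lower in the second, and 16 the reverse. The counts were 11 and 16 at 2 months and with CCl4, and 24 and 16 at 8 months and with CCl4. Spearman correlations of the differences across genes, which are not independent replicates, were 0.29, 0.26 and 0.25. Female-biased genes had 15 of 20 members at least 2-fold higher in DKO at 2 months, 6 at 8 months and 16 with CCl4. Independence is a low bar, since E1KO and E2KO exceeded it too: E1KO shared 26 higher genes at 2 and 8 months (1.04 by independence) and E2KO 6 (0.62). E2KO shared 10 lower genes there, beside 18 that were lower at 2 months and higher at 8 months and 5 that did the reverse. E1KO shared 27 lower genes at 8 months and with CCl4 (1.03), where its correlation of 0.25 equalled that of DKO. The correlations of E1KO were -0.23 and 0.041 for the other pairs, and those of E2KO -0.24, -0.011 and -0.026. E1KO had 124 genes higher and 130 lower at 2 months, 96 and 125 at 8 months and 137 and 94 with CCl4, and E2KO had 45 and 93, 157 and 162, and 48 and 66.

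The comparison of 8 with 2 months over the 4 genotypes asks what age changes. Summed microRNA and snoRNA entries also differed between these conditions (values under Other observations). A difference between libraries of the 2 ages therefore cannot be told apart from age. The lipid genes Cd36, Cidea, Cyp4a14 and Pdk4 rose, and the interferon-stimulated genes Ifi47 and Ifit1 and the secreted protein genes C8b, F11 and Plg fell. No list passed here with an estimated correlation. Among fatty acid oxidation genes 8 of 28 rose, and 17 adjusted over the list alone (median 0.43, camera adjusted p = 1.19e-09; adjusted p = 0.43 with an estimated correlation), with Cyp4a14, a PPAR-alpha target, at 3.77, Acot3 at 2.93, Acot1 at 1.59 and the starvation-induced kinase gene Pdk4 at 0.96. Among lipid droplet and uptake genes 8 of 24 rose and 2 fell (camera adjusted p = 0.00052; adjusted p = 0.573 with an estimated correlation). Cd36, a fatty acid transporter, rose by 2.67 (adjusted p = 0.00306), the lipid droplet gene Cidea by 2.5, Mogat1 by 2.06, Plin4 by 1.49 and the adipogenic regulator Pparg by 1.45, while Fabp5 (-3.25) and Lpl (-1.66) fell. All 30 interferon-stimulated genes were lower (median -0.50, camera adjusted p = 5.45e-11; adjusted p = 0.642 with an estimated correlation), 5 of them past the threshold, including Ifi47 (-1.29) and Ifit1 (-0.93). Of 27 secreted protein genes 3 fell, C8b (-1.47), F11 (-1.26) and Plg (-0.54; camera adjusted p = 2.3e-07; adjusted p = 0.642 with an estimated correlation). Male-biased genes were lower too (median -0.75, camera adjusted p = 8.72e-05; adjusted p = 0.101 with an estimated correlation).

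Among other genes at 8 months, Amd1 of polyamine synthesis rose by 2.49, Nat8 by 2.27, Clstn3 by 2.10, Wfdc2 by 2.01, the glutathione transferase gene Gsta2 by 2.13 and the lipogenic genes Me1 by 1.13 and Mlxipl by 0.90. Tff3 (-2.98, adjusted p = 0.000956), the crystallin gene Crybb3 (-1.99), the growth factor receptor gene Egfr (-1.82, 0.00707), the cadherin gene Cdh1 (-1.77) and the cytokine receptor gene Lifr (-1.71) fell. In all, limma called 308 genes higher and 181 lower. Without the 8-month column labelled E1KO it called 127, of which 122 were among these. With no filter on low values Cyp4a14, Cidea, Lpl, Amd1, Nat8, Crybb3 and Cdh1 lost their call. Without WT it called 54, without E1KO 63, without E2KO 240 and without DKO 147.

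CCl4, compared with 2 months over the 4 genotypes, brought out division, scar and immune genes and lowered hepatocyte metabolism. All 41 cell cycle genes rose, with 37 of 41 matrix and 25 of 28 macrophage genes. Of urea cycle genes 22 of 28 fell, with 18 of 32 P450 and 11 of 19 pericentral genes. No list passed here with an estimated correlation. The CCl4 groups were also 1 month older, and without an untreated group at 3 months age and CCl4 cannot be separated. limma called 3800 genes higher and 2794 lower, 933 and 486 of them by at least 2-fold. After rescaling the columns by median ratio the counts were 3143 and 3491, so which side is larger depends on the scale. All 41 cell cycle genes rose (camera adjusted p = 4.39e-14; adjusted p = 0.579 with an estimated correlation), among them Birc5 (4.42), the helicase genes Mcm6 (4.03) and Mcm5 (3.98, adjusted p = 8.03e-06) and Cdc20 (3.82). The p53 target Cdkn1a rose by 4.28, and Ezh2 rose by 1.44 (adjusted p = 0.000175). Of 41 matrix genes 37 rose, 38 adjusted over the list alone (camera adjusted p = 3.71e-09; adjusted p = 0.379 with an estimated correlation), with Timp1, an inhibitor of matrix breakdown, at 3.93, Col1a1 at 2.42 and Col3a1 at 1.91. Of 18 stellate cell markers 15 rose and 1 fell (camera adjusted p = 0.000253; adjusted p = 0.281 with an estimated correlation), including the contractile genes Acta2 (3.16) and Tagln (2.75). Of 28 macrophage markers 25 rose, such as Trem2 (3.08), Lyz2 (2.59) and Cd68 (2.23; camera adjusted p = 3.08e-06; adjusted p = 0.592 with an estimated correlation). Lcn2, an acute phase and neutrophil gene, rose by 3.66, and the fetal genes Ly6d by 5.05 and Afp by 3.50.

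On the falling side with CCl4, 22 of 28 urea cycle and amino acid genes passed, 23 adjusted over the list alone (median -1.06, camera adjusted p = 2.78e-08; adjusted p = 0.281 with an estimated correlation), among them Oat (-3.21) and Otc (-2.21). Of 32 P450 genes 18 fell and 2 rose (camera adjusted p = 0.0082; adjusted p = 0.605 with an estimated correlation). Cyp2e1, the enzyme that activates CCl4, fell by 3.25 (adjusted p = 0.00653), as did Cyp2a5 (-3.48), while Cyp2b10 rose by 2.56. Of 19 pericentral genes 11 fell and 2 rose (camera adjusted p = 0.00903; adjusted p = 0.605 with an estimated correlation), with the glutamate transporter gene Slc1a2 at -3.85 and the glutamine synthetase gene Glul at -2.80. Of 20 male-biased genes 13 fell (median -1.19, camera adjusted p = 1.75e-05; adjusted p = 0.0732 with an estimated correlation), such as the steroid dehydrogenase gene Hsd3b5 (-3.36). Cyp2d13 (-3.17), Upp2 (-3.08) and Ces3b (-3.06) fell too. Bile acid genes were lower as a list, 13 of 20 past the threshold (camera adjusted p = 0.00342; adjusted p = 0.513 with an estimated correlation). Stmn1 rose by 4.03, Pbk by 3.83 and Cyp4a14 by 4.35.

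The DKO-by-condition fit answers whether the DKO difference itself changes with age or with CCl4. In this fit that difference is from the average of WT, E1KO and E2KO, not from WT alone. At 8 months the difference was larger than at 2 months for Ly6d, Anxa13, Cd24a and Cdkn2a, and more negative or smaller for Slco1a1, Hao2 and Cyp2b9. limma called 21 genes higher and 7 lower, with 492 at an unadjusted p under 0.05. The change in the DKO difference was 5.93 for Ly6d, a surface marker (adjusted p = 0.00628), with 142.3 FPKM in DKO and 2.07 in WT at 8 months. It was 2.57 for the annexin gene Anxa13 (0.00474), 1.49 for Cd24a (0.0176) and 1.83 for Cdkn2a (0.0107). It was -5.0 for the organic anion transporter gene Slco1a1 (0.0053), at 124.0 FPKM in WT and 1.07 in DKO at 8 months. It was -4.02 for the oxidase gene Hao2 (0.00144), at 27.1 FPKM in DKO at 2 months and 4.51 at 8 months. For Cyp2b9 it was -3.78 (0.00757). There WT went from 0.09 to 14.8 FPKM, while DKO was 27.4 at 2 months and 25.1 at 8 months. Cholangiocyte and progenitor markers were higher as a list, with 2 of 18 past the threshold over all genes, and 9 larger and 1 smaller adjusted over the list alone (median 0.70, camera adjusted p = 7.04e-12; adjusted p = 0.046 with an estimated correlation). The filter favours this too: 4 of the 18 passed it only through the DKO columns, and the other 14 had a median of 0.51, with 11 larger and 1 past the threshold. Female-biased genes split, with a larger DKO difference in 3 and a smaller one in 5 (median -1.10, camera adjusted p = 7.57e-07; adjusted p = 0.147 with an estimated correlation). With a pseudocount of 0.1 the fit called 3 genes at 8 months, Hao2, Mir191 and Slco1a1, so that Ly6d, Anxa13, Cd24a, Cdkn2a and Cyp2b9 all lost their call. The residual spread comes from the WT, E1KO and E2KO columns, so DKO is assumed to vary like these.

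With CCl4 the DKO difference was larger than at 2 months for the pericentral genes Slc1a2 and Glul, while cell cycle genes were lower as a group with none passing alone. No list passed here with an estimated correlation. limma called 25 genes higher and 8 lower for DKO by CCl4, with 1047 at an unadjusted p under 0.05. The change in the DKO difference was 3.42 for Slc1a2 (adjusted p = 0.0179) and 2.23 for Glul (0.0471). Cyp2e1 was 3857 FPKM in DKO with CCl4 and 463.7, 151.1 and 386.1 in WT, E1KO and E2KO, and Glul was 137.9 against 28.1, 22.6 and 36.8. Of 19 pericentral genes, 2 passed over all genes and 10 adjusted over the list alone, and 8 were at least 2-fold higher and 1 lower in DKO with CCl4 (median 1.24, camera adjusted p = 5.42e-09; adjusted p = 0.229 with an estimated correlation). All 41 cell cycle genes had negative differences (median -1.09, camera adjusted p = 1.84e-27; adjusted p = 0.229 with an estimated correlation), with 0 passing over all genes and 28 adjusted over the list alone. Mki67, a proliferation marker, was 9.83 FPKM in WT and 2.71 in DKO with CCl4, and Top2a 19.6 and 6.07. The change was -2.14 for the contractile gene Tagln (0.0471), and Acta2 was 6.98 FPKM in DKO against 37.6 in WT. It was 2.37 for Gpc3 (0.0093), 1.91 for Cdkn2a (0.0148), 2.79 for Socs3, 1.75 for Hoxa10 (0.0106) and -7.31 for Serpina3c. With a pseudocount of 0.1 the fit called 7 genes with CCl4; Slc1a2 and Serpina3c stayed among them, while Glul, Tagln, Gpc3, Cdkn2a, Socs3 and Hoxa10 lost their call.

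**Figure D3:**
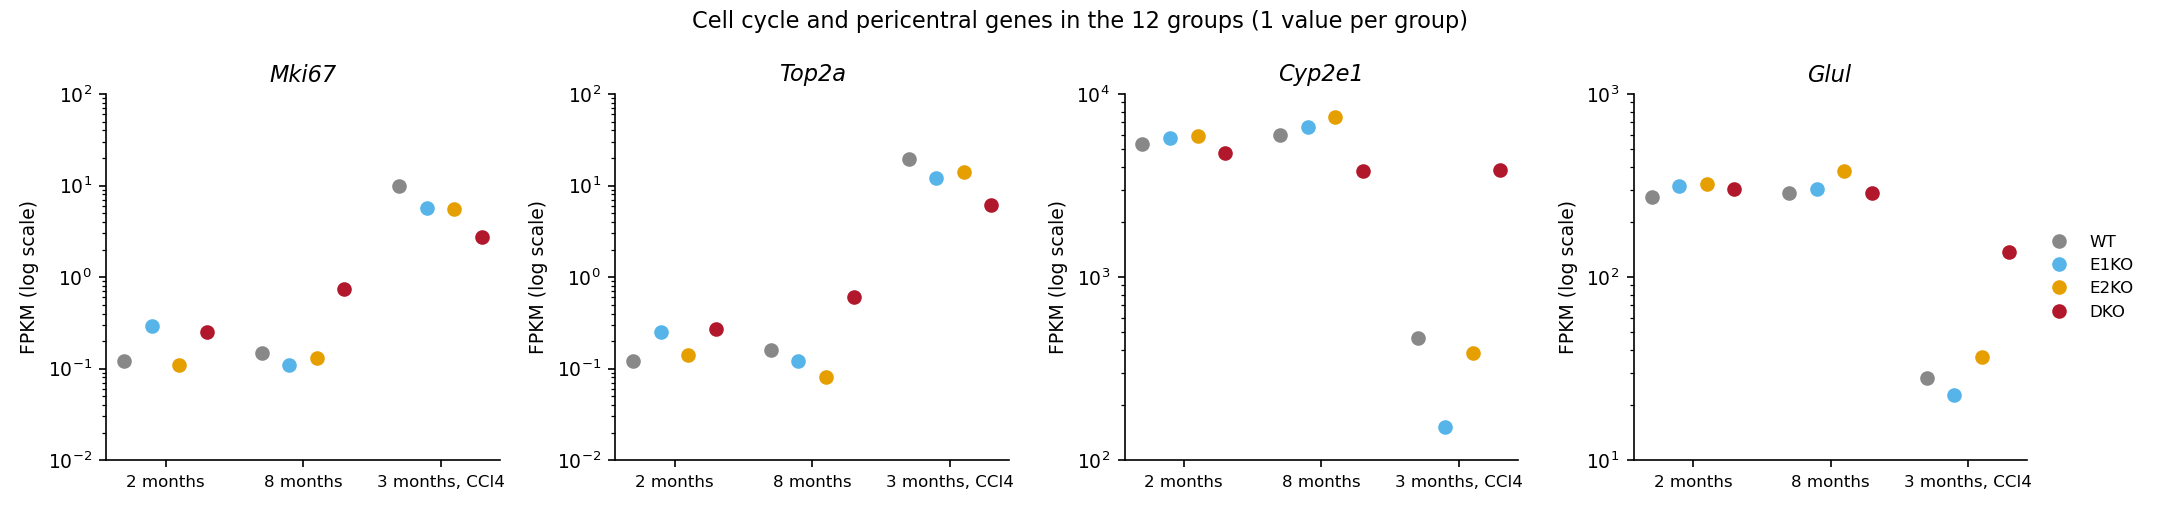
Points show FPKM on log axes for the cell cycle genes Mki67 and Top2a and the pericentral genes Cyp2e1 and Glul in the 12 groups, 1 value per group. With CCl4, DKO had the lowest Mki67 (2.71) and Top2a (6.07) and the highest Cyp2e1 (3857) and Glul (137.9) of the 4 genotypes.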

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

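The tests of an intact Ezh1 allele, of striated muscle, of a milder CCl4 response and of called genes on other chromosomes were chosen after the result was seen; all others below were set beforehand, though the chromosomes of the genes called for E1KO were known when the linkage test was written. Chance puts about 1 in 20 groups past the criterion for a column far from the rest.

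In the 6 columns labelled E1KO or DKO, the 8-month column labelled E1KO stood far from the rest on Ezh1 (0.88 FPKM, a gap of 0.744 of the range, past Dixon's 95% critical value) and on summed skeletal muscle genes (416.9 FPKM, a gap of 0.999). Striated muscle in the sample is a candidate explanation for the second: 9 of 11 muscle genes were at 1 FPKM or more and at least 10 times the highest other column, led by Acta1 at 128.9, Tnnc2 at 65.8 and Tnnt3 at 63.5, and whether muscle also carries the Ezh1 signal was not tested. An animal with an intact Ezh1 allele may instead be in the group: on a scale from the DKO level (0) to the intact level (1), Ezh1 lay at 0.371 and the 3 marker genes at a median of -0.00279 (AA465934 0.264, Cd1d2 -0.00279, Gm11968 -1.62). All 3 lie below 0.371, as do 5 of 5 at a limit of 3-fold (median -0.00757), 5 of 6 at 2.5-fold (-0.00518, interval -1.62 to 0.627) and 6 of 9 at 2-fold (0.238, -0.083 to 0.92); 3 or 5 markers give no interval and the others hold 0.371, so this explanation cannot be told from the markers, though Cd1d2 at 0.04 FPKM (DKO 0.05, WT 6.01) goes against it if that gene follows the allele. Whether Cd1d2 follows the allele is uncertain, since it lies on chromosome 3 and Ezh1 on chromosome 11. In E2KO at 8 months Cd1d2 was 1.27 FPKM. No biological explanation was tested for this column.

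Cell cycle genes responded less to CCl4 in DKO, with a DKO-by-CCl4 median of -1.09 and 41 of 41 genes lower. All intervals here run over genes within single columns, which are not independent replicates, and give no spread between animals. The scale of the authors' columns is argued against, since after rescaling by median ratios the median was still -1.09 (95% interval -1.29 to -0.80). A milder response of every gene stays open: macrophage, endothelial and matrix genes together reached 80.6% of the response in the other genotypes (72 to 94.3), against 57.4% for the cell cycle genes (52.6 to 63.2), but the gap of 23.2 points, though wider than in WT (-43.0) and E2KO (6.93), is narrower than in E1KO (31.6). Macrophage genes alone were at 110% (85.8 to 119), while endothelial genes at 62.3% (41.0 to 86.1), matrix genes at 71.7% (53.7 to 91.5), stellate markers at 72.2% (34.7 to 119), urea cycle genes at 66.5% (50.5 to 91.6) and P450 genes at 49.9% (19.4 to 87.1) overlap the cell cycle genes, and pericentral genes were at 14.2% (-33.0 to 39.9). An effect of genotype on regeneration may be the source, as a hypothesis, and a different time since the injection, a milder injury and the single DKO column stay open.

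In the contrast of the Ezh1-null columns (mean of E1KO and DKO) with the others, 135 genes were higher and 84 lower; the average also holds genes that differ in DKO alone, such as Sult2a1. A chromosome segment linked to the Ezh1 null allele could raise such calls near Ezh1 in this mixed background. Of the 400 tested genes nearest Ezh1 on chromosome 11, 10 (2.5%) were called against 207 of 10922 others (1.90%), an odds ratio of 1.33 (95% interval 0.622 to 2.52, Fisher's exact test p = 0.352). The 195 called genes on other chromosomes do not lie in a segment linked to Ezh1. Their number cannot show whether such a segment acts on them from a distance, and unlinked segments of the mixed background were not tested. For the 22 on chromosome 11 the interval still allows an enrichment above 2, and linkage cannot be told apart from loss of Ezh1. Loss of Ezh1, alone or together with Ezh2, stays open as the biological explanation.

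In the DKO-by-condition fit DKO was compared with the average of WT, E1KO and E2KO. The DKO difference at 8 months was tested against that at 2 months and differed in 28 genes. Of those named by the rule, it was larger for Ly6d (5.93), Anxa13 (2.57), Sult2a2 (2.23), Sult2a1 (1.83), Cdkn2a (1.83) and Pnliprp1 (1.22), smaller for Hao2 (-4.02), Cyp2b9 (-3.78) and A1bg (-2.23), and more negative for Slco1a1 (-5.0). With CCl4 the DKO difference, tested against that at 2 months, differed in 33 genes. Of those named by the rule, it was larger for Slc1a2 (3.42), Sult2a2 (2.74), Gpc3 (2.37), Cdkn2a (1.91), Sult2a1 (1.90), Hoxa10 (1.75), Hoxc10 (1.42), Hoxd9 (1.37), Hoxd8 (1.32) and Gsc (1.10), while for Serpina3c it went from positive to negative (-7.31). With a pseudocount of 0.1, only Hao2 and Slco1a1 of the genes named here kept their call at 8 months. With CCl4 only Slc1a2 and Serpina3c kept theirs. The Hox genes passed the filter only through the DKO columns.

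Labels were regrouped 100 times, the real grouping included, with genotype labels moved within conditions or condition labels within genotypes. For DKO against WT, only the real grouping gave as many as 299 genes (highest other 112). For DKO against E2KO, only the real one gave as many as 348 (highest other 132). The same held for CCl4 against 2 months (6594, highest other 6326) and, by a narrow margin, for DKO by CCl4 (33, highest other 29). A share of 1 in 100 is the smallest this check can give, and no share is corrected over the 9 comparisons. Chance is therefore not excluded for them. In 3 comparisons another regrouping called more genes than the real one, so their shares, though small, are not read as excluding chance: 8 against 2 months (489, 3 of 100, highest other 6093), DKO by 8 months (28, 2 of 100, highest other 29) and E1KO against WT (2, 4 of 100, highest other 170). Chance is not excluded for E2KO against WT (limma called 0 genes, with 155 at an unadjusted p under 0.05; 100 of 100, highest other 230) or for the non-additivity (4 genes, 5 of 100, highest other 24). Some regroupings called several times the real count (170 for E1KO, 230 for E2KO, 24 for the non-additivity, 6093 for 8 months). A regrouping can gather DKO columns, or CCl4 columns, under another label. The regroupings thus hold the real differences of other groups and are not free of them for these comparisons. Which columns each draw gathered was not tabulated.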

How the results depend on the processing

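Leaving out the 8-month column labelled E1KO was chosen after the data were seen; every other alternative here was planned. No paired analysis of animals was possible because each group has 1 column; columns are matched by condition only, which every fit across conditions holds as a block. Across alternatives, 55 of 105 counts of genes stayed within 1.5 times the reported count and 50 moved. Of 1872 values for single named genes, 1530 counted as unchanged, 323 fell short of the threshold, 6 newly passed it, 13 without a test moved and 0 reversed. Of 1224 single list results 1075 counted as unchanged, 131 fell short, 17 newly passed and 1 reversed. A change of sign in a gene or list called in neither fit counted as unchanged. Genes named from the contrasts had the same sign in every condition or genotype, so leaving out 1 of these could not reverse them.

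Rescaling the columns, and eBayes without trend, kept every count of genes within 1.5 times. Rescaling shifted the median CCl4 difference of all genes by -0.097 and took the higher share of the calls for 3 months with CCl4 against 2 months, genes across genotypes, from 57.6% to 47.4%. A pseudocount of 0.1 left 3 genes for DKO by condition: 8 months, and 7 for DKO by condition: 3 months with CCl4. No filter on low values gave 328 and 300. The cause was not tested.

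Leaving out 1 condition gave 23 to 37 genes for DKO against WT, genes across conditions, 0 to 4 for E1KO against WT, genes across conditions, 23 to 47 for DKO against E2KO, genes across conditions, and 1 to 9 for the non-additivity of Ezh1 and Ezh2 loss. E2KO against WT stayed at 0 by limma, with 155 genes at an unadjusted p under 0.05 in all columns. Leaving out 1 genotype gave 54 to 240 genes for 8 months against 2 months, genes across genotypes, and 5212 to 6130 for CCl4. With only the WT and DKO columns, blocked by condition, 5 genes passed. These fits hold fewer columns.

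Without the 8-month column labelled E1KO, 4 genes passed for E1KO against WT, 1 for the non-additivity (0 of the 4 reported) and 127 for 8 months. DKO against WT called 205, of which 188 were among the reported ones, and DKO against E2KO 231, of which 215 were. Macrophage and Kupffer cell markers reversed in the non-additivity (camera adjusted p = 0.0013, from 0.89 with all columns).

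For DKO against WT within each condition, a size of 1.5-fold gave 1123 genes at 2 months, 1294 at 8 months and 1587 at 3 months with CCl4, 4-fold gave 110, 147 and 144, and a pseudocount of 0.1 gave 720, 951 and 961. Genes higher at both 2 and 8 months numbered 289 at 1.5-fold (43.7 by independence), 20 at 4-fold and 267 with a pseudocount of 0.1 (31.0), and lower 132 at 1.5-fold (21.6) and 16 at 4-fold. At 2 months and with CCl4 they numbered 258 (44.7), 20 and 199 (22.2) higher, and 117 (33.8), 6 and 59 (9.37) lower, in the same order. At 8 months and with CCl4 they numbered 305 (58.9), 27 and 240 (36.7) higher, and 112 (32.2) and 7 lower. These follow from the size rule and the weight of low values.

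With an estimated correlation, the lists called fell from 17 to 2 for DKO against WT, 7 to 0 for E1KO, 14 to 0 for E2KO, 19 to 2 for DKO against E2KO, 12 to 1 for the non-additivity, 11 to 0 for 8 months, 13 to 0 for CCl4, 23 to 1 for DKO by 8 months and 12 to 0 for DKO by CCl4. Rescaling and the pseudocount kept all counts of lists within 1.5 times. The depth is unknown, so what it limits cannot be given.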

Other observations

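All values in this part were chosen after they were seen, and no explanation of them was tested.

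Clock-controlled genes differed between columns of 1 condition. At 2 months, Dbp was 35.1, 74.2, 60.0 and 76.2 FPKM in WT, E1KO, E2KO and DKO, and Usp2 was 9.94, 24.8, 8.08 and 22.6. The time of day of sampling is not given in the sources used here.

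Acute phase and metallothionein genes varied widely between columns. At 2 months, Saa2 was 2175 FPKM in WT and 54.3, 260.4 and 80.2 in E1KO, E2KO and DKO, and Mt1 was 1825 in WT and 221.7, 60.4 and 281.3 in the others.

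Several genes followed Ezh1 status in every condition. Cd1d2 was 3.26 and 4.65 FPKM in WT and E2KO at 2 months and 0 and 0.02 in E1KO and DKO, and at most 0.08 in the Ezh1-null columns of the other conditions. Accn5 was 34.2 and 43.1 FPKM in WT and E2KO at 2 months and 4.07 and 2.32 in E1KO and DKO. At 8 months E2KO lay below WT, at 1.27 against 6.01 FPKM for Cd1d2 and 11.9 against 52.7 for Accn5. Cd1d2 and Accn5 lie on chromosome 3, while Ezh1 lies on chromosome 11. An unlinked segment of the mixed background was not tested for them. Ddit4, a stress-induced inhibitor of mTOR signalling, was 4 and 3.76 FPKM in WT and E2KO at 2 months and 19.3 and 20.1 in E1KO and DKO.

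The imprinted fetal RNA H19 was 2.52, 2.27 and 6.96 FPKM in DKO at 2 months, 8 months and with CCl4, and at most 0.16 elsewhere except for 13 in the 8-month column labelled E1KO. The table also lists 720 microRNA and snoRNA entries, whose sum ran from 5877 to 23891 FPKM between columns. The sum was 6179 to 6612 in the 2-month columns and 9655 to 12354 with CCl4. At 8 months it was 16844 to 23891, except for 5877 in the column labelled E1KO. These entries made up 5 of the 489 calls for age and 33 of the 6594 for CCl4.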
